A study of Mus musculus with 32 samples.

How the data were processed

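The measurement was poly(A) RNA-seq of mouse kidney in 32 libraries, 4 in each of 8 groups. Per the labels' protocols, frozen and powdered kidneys of male C57BL/6 mice were used, RNA was taken with ISOGEN II, and libraries were made with a NEBNext Ultra Directional kit. Per the submitters' processing notes, sequencing was on a NextSeq 500 and the genome was mm10. The annotation release, the strand setting used in counting and the settings of the read mapping are not given in the sources used here. Per the labels, each host received a kidney transplant, kept its native kidney, and received LMB2 or vehicle through the tail vein.

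The authors deposited a single table of 49585 genes and 913 columns. Per the file headers its per-sample values include integer counts of reads per gene. The deposited count used here was the total of exon and intron reads assigned to a gene, which equalled the authors' own expression value in all 32 libraries. Of 480 per-sample value columns, 160 were read and 320 were not used. The authors also deposited, per the file headers, a signed fold change and an FDR-corrected p-value for each of the 4 comparisons of LMB2 with vehicle, from an EDGE test with tagwise dispersions. Those p-values were used only for the numbers of genes under 0.05 set beside the numbers found here. The direction of the deposited fold (vehicle over LMB2) was read from the counts of the same table.

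The comparisons were LMB2 against vehicle in the graft and in the native kidney of W-to-N and of N-to-N mice, the difference of the LMB2 response between N-to-N and W-to-N grafts, and that between native and graft kidneys of W-to-N mice. Under vehicle they were graft against native kidney of W-to-N mice, and N-to-N against W-to-N grafts. These 8 comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Each of the 4 comparisons of LMB2 with vehicle, and each of the 2 under vehicle, was fitted on its own 8 libraries, and each difference of responses on its 16. The model was edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low counts, robust quasi-likelihood tests, and Benjamini-Hochberg adjustment at 0.05. SE of a log2 change was derived from the quasi-likelihood F value. A prior count of 2 was used for log2 values, and an offset of 0.5 CPM for log2 values in permutation tests.

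The number in each title was read as the host mouse, so that the graft and the native library with the same number in the same group came from 1 of 16 mice. This reading was checked with the residuals of genes after group means were removed: the graft and native libraries of a mouse correlated at r from -0.107 to 0.472 across genes, over 0.1 in 9 of 16 pairs, and 12 of 16 had their own partner as the best match. Genes are not independent replicates. No comparison of LMB2 with vehicle contained both kidneys of a mouse, and a term for the mouse was an alternative in the 2 comparisons that did. Replicate numbers of LMB2 and vehicle groups had r from -0.17 to 0.162, with 5 of 16 libraries matching their own number best. In the W-to-N native kidney all 4 were positive (0.0848 to 0.162) and 3 of 4 matched best, so a pairing by number is not excluded there. A block by that number was kept as a further setting fixed in advance, and took the count of that kidney from 92 to 392.

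Gene lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01 between genes, with adjustment over the 34 lists, again with a correlation estimated from the data, and with fry. The lists were podocyte, glomerular and vascular endothelium, proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct, sodium transport and its regulators, renin-angiotensin system, tubular injury, macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil, MHC class II and antigen presentation, interferon response, chemokines and cytokines, complement, fibrosis and matrix, cell cycle, fatty acid oxidation, cholesterol synthesis, mitochondrial respiratory chain, unfolded protein and integrated stress response, oxidative stress and NRF2, p53 targets, hypoxia and glycolysis, circadian clock, immediate early, and 6 lists for tissue that can adhere to a kidney or remain in it: erythroid and blood, adipose, adrenal, skeletal and smooth muscle, urothelium and liver. Some genes stood in more than 1 list, such as Lcn2 in the tubular injury and neutrophil lists and Slc4a1 in the collecting duct and erythroid lists. Hspa1a and Hspa1b were members of the immediate early list.

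Genes named in the text were, for each comparison, the 6 largest rises and the 6 largest falls among genes past the threshold whose libraries were completely separated, with a mean of at least 1 CPM and without numbered, unnamed and ribosomal protein genes. Added were up to 3 members of smallest p from each list with a call (1 from the lists for adhering tissue), and always Nphs1, Havcr1, Lcn2, Agt, Ren1, Scnn1a, Scnn1b and Scnn1g. Of the list members under that rule, those that passed the threshold are named. Podxl and Synpo belonged to a planned check of 5 podocyte genes, with Nphs1 and Wt1. Results of some genes under these rules are not reported here. Nes, Ehd3 and Esm1 beside the lists they belong to, and Banp, Sema3f, Inhbb, Hsph1, Prlr, Slco1a1, Idi1 and Kap across comparisons were named after their values were seen, as were other genes given in the closing observations. Identifiers and positions are those of the deposited table, and 99.48% of its identifiers matched GENCODE M21.

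Depth was 10577056 to 20622097 reads assigned to genes per library. A gene with no reads in a whole group was given a floor of 3 reads per library. The floor reflects the counting of reads alone, and reads without molecular identifiers are not independent molecules. SEs of log2 changes come from a fit that includes the spread between libraries, and SDs are the spread over libraries or mice. The method was tested on simulated data with 200 changed genes. Comparisons of LMB2 with vehicle found 66.1 to 75% of genes changed 1.5-fold, 84.1 to 91.1% at 2-fold and 97.2 to 100% at 4-fold. Of their calls 4.86 to 10.2% were false. The differences of responses found 31.9 to 34.8% at 1.5-fold, 63.9 to 75% at 2-fold and 92.5 to 98.6% at 4-fold. In the same test on the W-to-N graft, DESeq2 gave 15.5% false calls. With no changed list camera called 0 of 34 simulated lists, and with podocyte genes halved it called 1. Simulated genes were drawn independently, so this check does not cover lists whose genes vary together.

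Settings also tried were scaling by library totals and by DESeq2 size factors, DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, a threshold of 0.01, a 2-fold minimum, a block by replicate number or mouse, a fit over all 8 groups (16561 genes), fry and an estimated correlation for lists, and leaving out each library. Alternatives chosen after seeing the data were unique exon reads, total exon reads, a correction for transcript length (loess, span 0.4), that correction with the block, an estimated correlation with the block, and limma-voom. For a gene that was not called and whose estimate lay within 1 SE of 0, the direction was treated as undetermined under the alternatives. Tables were read with Python 3.11.15 and pandas 2.3.3, with numpy 2.4.6, and the plot was drawn with matplotlib 3.10.9. No sample was left out.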

Results

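The data were poly(A) RNA-seq counts from 32 mouse kidney libraries in 8 groups of 4. Every host was a NEP25 mouse, a transgenic line whose podocytes carry human CD25, and each host had a transplanted kidney (the graft) beside a kidney of its own (the native kidney). In W-to-N mice the donor was wild type, so that the native podocytes carried human CD25 and those of the graft did not. In N-to-N mice the donor was a NEP25 mouse, so that podocytes of both kidneys carried it. Hosts received LMB2, an immunotoxin directed at human CD25, at 1.75 ng/g, or vehicle, and both kidneys were taken on day 8. The design asks how podocyte injury in a mouse affects a kidney whose own podocytes are not the target. Reads assigned to genes per library were 15076254 to 17081856 under LMB2 and 15398127 to 20184456 under vehicle in the W-to-N graft. They were 10577056 to 20344252 and 16664650 to 19037517 in the N-to-N graft, 15524771 to 16544760 and 17778633 to 20035165 in the W-to-N native kidney, and 16504150 to 19980411 and 16661289 to 20622097 in the N-to-N native kidney. The mean share of intron reads was 5.79 to 8.27% by group, and the mean share of mitochondrial reads was 10.9 to 13%. Levels below are means ± SD over 4 libraries in CPM, the reads of a gene scaled to a common library total, log2 changes are LMB2 over vehicle ± SE unless stated, and positions are in mm10.

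The podocyte genes Nphs1 and Wt1 fell under LMB2 in both kidneys of N-to-N mice. Nphs1 encodes the slit diaphragm protein nephrin (ENSMUSG00000006649, chromosome 7, 30458314 to 30487223). It fell from 48.2 ± 3.56 to 25.4 ± 4.54 CPM in the N-to-N native kidney and from 49.1 ± 9.59 to 27.9 ± 2.49 CPM in the N-to-N graft. It stood at 31.1 ± 6.85 against 47.9 ± 8.68 CPM in the W-to-N native kidney, and at 37.5 ± 2.19 against 36.9 ± 5.06 CPM in the W-to-N graft. Wt1, a transcription factor of podocytes (ENSMUSG00000016458, chromosome 2, 105126528 to 105173616), was at 4.98 ± 0.849, 5.46 ± 1.05 and 7.20 ± 1.94 CPM under LMB2 in those first 3 kidneys, against 13.8 ± 1.31, 13.6 ± 2.75 and 11.8 ± 1.43 CPM under vehicle. Wt1 was at 13.5 ± 0.68 against 13.2 ± 1.79 CPM in the W-to-N graft. Podxl, which encodes podocalyxin, was at 246 ± 22.2 against 294 ± 5.75 CPM, and Synpo, which encodes synaptopodin, at 61.3 ± 6.41 against 82.1 ± 5.83 CPM in the N-to-N native kidney (adjusted p = 0.0482 and 0.00813). In the other 3 kidneys neither of these genes passed. Over 5 podocyte genes in 4 kidneys, an exact permutation test cannot give a p below 0.0286 with 4 against 4 libraries. Complete separation gave that p, and an adjusted exact p of 0.052. The only rise among the results with that p was Podxl in the W-to-N graft, at 279 ± 6.19 against 251 ± 22.8 CPM (adjusted p = 0.319 with edgeR).

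**Figure D1:**
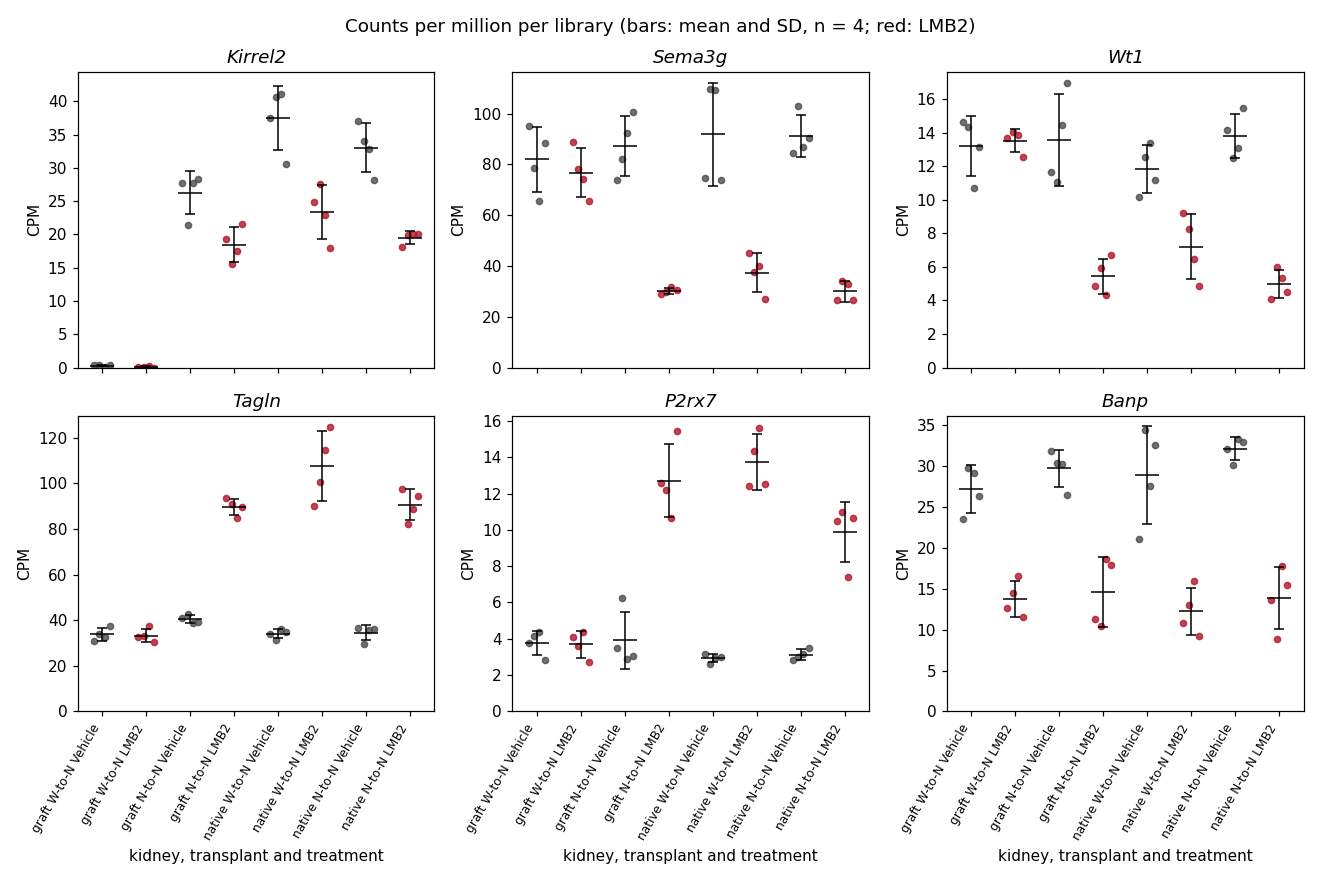
CPM of 6 genes (Kirrel2, Sema3g, Wt1, Tagln, P2rx7 and Banp, 1 panel each) in the 8 groups: points are libraries, bars are mean and SD (n = 4), red is LMB2 and grey is vehicle. Sema3g under LMB2 averaged 30.0 CPM in the N-to-N native kidney and 76.7 CPM in the W-to-N graft, and Kirrel2 averaged under 1 CPM in the W-to-N graft in both treatments.

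In the native kidneys of N-to-N mice 13 of 25 podocyte and 9 of 15 distal convoluted and connecting tubule genes fell under LMB2. Rises were called in 10 of 22 chemokine and cytokine, 15 of 31 tubular injury, 7 of 32 fibrosis and matrix and 14 of 29 cell cycle genes. With an estimated correlation the last 3 of these lists did not pass (adjusted p = 0.0729, 0.0729 and 0.125). Tagln, which encodes the actin-binding protein transgelin (ENSMUSG00000032085, chromosome 9, 45929618 to 45936058), rose from 34.5 ± 3.35 to 90.6 ± 6.79 CPM, a log2 change of 1.39 ± 0.0788 (adjusted p = 9.15e-07). Havcr1, which encodes the tubular injury marker KIM-1 (ENSMUSG00000040405, chromosome 11, 46735079 to 46779578), rose from 0.324 ± 0.0477 to 26.2 ± 11.4 CPM, a log2 change of 6.30 ± 0.621 (adjusted p = 0.0039). Wt1 fell by 1.47 ± 0.127 on the log2 scale (adjusted p = 2.83e-05) and Nphs1 by 0.92 ± 0.108. Ren1, which encodes renin, rose from 103 ± 12 to 194 ± 20.2 CPM, a log2 change of 0.92 ± 0.0928 (adjusted p = 0.000168).

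Of 15352 genes tested in the N-to-N native kidney 381 rose and 241 fell, 109 and 25 of them at least 2-fold. At an unadjusted p under 0.05 there were 2639, and the authors' own test listed 359 genes, of which 309 were also called here. The other largest rises were Krt20 (log2 change 4.40 ± 0.414), Serpina10 (3.75 ± 0.261), Cxcl1 (3.71 ± 0.544) and Timp1 (3.53 ± 0.348). Saa1, an acute phase gene, had 0 reads in all 4 vehicle libraries and 2.29 ± 1.49 CPM under LMB2, at least 12.2-fold higher than a floor of 3 reads per library. Saa1 passed in 10 of 18 alternatives, with adjusted p up to 0.127, and did not pass with unique exon reads (adjusted p = 0.071). The largest falls were the podocyte gene Ddn, which encodes dendrin (ENSMUSG00000059213, chromosome 15, 98803781 to 98807925), from 13.1 ± 1.88 to 2.53 ± 1.15 CPM (log2 change -2.36 ± 0.241), Zbtb16 (-2.03 ± 0.405), Hspa1a (-1.92 ± 0.307), Hspa1b (-1.91 ± 0.35) and Sema3g (-1.60 ± 0.0939). Hspa1a and Hspa1b are heat shock genes of nearly the same sequence. They passed in 13 and 12 of 19 alternatives, Zbtb16 in 6, and Ddn and Sema3g in 19. Without LMB2 library 1 or 4 the count of 622 became 290 or 320, and without vehicle library 1 or 3 it became 379 or 325.

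Of 25 podocyte genes measured in the N-to-N native kidney 13 fell and 1 rose (16 and 2 when adjusted over the list alone, list test adjusted p = 1.31e-29, and adjusted p = 0.0497 with an estimated correlation). The gene that rose was Nes, which encodes the intermediate filament nestin. Of 15 distal convoluted and connecting tubule genes 9 fell (11 when adjusted over the list alone, adjusted p = 1.33e-16, and adjusted p = 0.0497 with an estimated correlation). Among them were the magnesium channel gene Trpm6 (log2 change -0.94 ± 0.12), the sodium-calcium exchanger gene Slc8a1 (-1.14 ± 0.176) and the thiazide-sensitive transporter gene Slc12a3, from 961 ± 25.3 to 741 ± 83.1 CPM. Slc12a1, Kcnj1 and Ppp1r1a of the thick ascending limb had log2 changes of -0.38 ± 0.0762, -0.38 ± 0.0717 and -0.32 ± 0.0639. They were the 3 of 14 genes of that list that fell (8 when adjusted over the list alone, adjusted p = 3.41e-05, and adjusted p = 0.0497 with an estimated correlation). Of 19 collecting duct genes 6 fell (7 when adjusted over the list alone, adjusted p = 5.41e-08, and adjusted p = 0.0823 with an estimated correlation). Among them were Fxyd4 (log2 change -0.57 ± 0.102), Hsd11b2 (-0.41 ± 0.0749) and the anion exchanger gene Slc4a1 (-0.66 ± 0.117). Sodium transport genes fell in 7 of 31 (12 when adjusted over the list alone, adjusted p = 3.48e-06, and adjusted p = 0.211 with an estimated correlation). Scnn1g, a subunit of the epithelial sodium channel, fell from 59.7 ± 8.38 to 47.3 ± 1.36 CPM (adjusted p = 0.0364). Scnn1a and Scnn1b had log2 changes of -0.01 ± 0.0668 and -0.24 ± 0.0705 (adjusted p = 0.972 and 0.0847).

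Tubular injury genes rose in 15 of 31 in the N-to-N native kidney (21 when adjusted over the list alone, adjusted p = 5.25e-32, and adjusted p = 0.0729 with an estimated correlation). Lcn2, which encodes the injury marker NGAL, rose from 1.89 ± 0.235 to 20.7 ± 8 CPM. Cell cycle genes rose in 14 of 29 (27 when adjusted over the list alone, adjusted p = 1.24e-26, and 0.125 with an estimated correlation). The mitotic genes Hmmr and Tpx2 had log2 changes of 2.40 ± 0.313 and 2.39 ± 0.366 and Cenpf at 1.85 ± 0.348. Of 32 fibrosis and matrix genes 7 rose (11 when adjusted over the list alone, adjusted p = 2.2e-19, and 0.0729 with an estimated correlation). The intermediate filament gene Vim rose by 1.09 ± 0.0682. Chemokines and cytokines rose in 10 of 22 (11 when adjusted over the list alone, adjusted p = 1.8e-11, and 0.0497 with an estimated correlation). Cxcl10 was at 1.48 ± 0.274, Il34 at 0.93 ± 0.135 and Cx3cl1 at 0.43 ± 0.0718. Immediate early genes rose in 6 of 22, with Egr1 at 2.44 ± 0.162, Egr2 at 2.88 ± 0.408 and Fos at 1.80 ± 0.358. The 2 that fell were Hspa1a and Hspa1b (7 and 2 when adjusted over the list alone, adjusted p = 3.46e-09, and adjusted p = 0.176 with an estimated correlation). Of 19 complement genes C3 and C4b rose (log2 changes 2.88 ± 0.402 and 1.09 ± 0.173, 4 when adjusted over the list alone, adjusted p = 3.41e-05, and adjusted p = 0.125 with an estimated correlation).

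Immune cell lists in the N-to-N native kidney held few calls. Of 21 macrophage genes Cd14 rose (log2 change 0.89 ± 0.157) and Csf1r, which encodes the receptor of colony stimulating factor 1, fell by 0.23 ± 0.0553 (list higher, adjusted p = 0.00139, and adjusted p = 0.458 with an estimated correlation). The neutrophil list of 3 genes (adjusted p = 0.000937) rested on Lcn2, and the MHC class II list of 16 had no call of a gene (adjusted p = 0.00775). With an estimated correlation they had adjusted p = 0.125 and 0.537. The respiratory chain list of 24 was lower with no gene called (adjusted p = 0.00082, and 0.537 with an estimated correlation). The share of mitochondrial reads was also lower in every LMB2 library of this kidney, at 11.52 to 12.14% against 12.15 to 13.42% under vehicle. The cholesterol list of 24 was also lower, though its only call was a rise (adjusted p = 0.0117, and 0.609 with an estimated correlation). Among the lists for adhering tissue, liver (9 genes, Ttr 0.53 ± 0.118, adjusted p = 0.000937) and adrenal (2 genes, Akr1b7 1.36 ± 0.193, adjusted p = 0.0283) were higher. Urothelium (9 genes, no call, adjusted p = 0.0132) and erythroid (8 genes, Slc4a1, adjusted p = 0.0418) were lower. With an estimated correlation these 4 had adjusted p = 0.125, 0.172, 0.375 and 0.375. With 1 library left out the MHC (LMB2 library 4 or vehicle library 3, adjusted p up to 0.0778), cholesterol (vehicle library 1, 0.285) and adrenal lists (LMB2 library 4 or vehicle library 3, up to 0.0858) ended. So did urothelium (LMB2 library 2 or vehicle library 4, up to 0.0936) and erythroid lists (LMB2 library 3 or 4 or vehicle library 2 or 3, up to 0.354).

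The other 14 lists did not pass in the N-to-N native kidney. Endothelium (adjusted p = 0.0613) had 3 genes up, Cd34, Tek and Plvap (0.39 ± 0.0674, 0.33 ± 0.0571 and 0.34 ± 0.0616), and Ehd3 and Esm1 down. Hypoxia (0.273) had Adm up (0.95 ± 0.11) and Pkm down (-0.35 ± 0.0687), proximal tubule (0.292) had Gatm down (-0.53 ± 0.112), and p53 targets (0.387) had Sesn2 up. The renin-angiotensin list (0.576) had Ren1 up, with Agt, which encodes angiotensinogen, at 0.08 ± 0.136 (adjusted p = 0.845). The unfolded protein list (0.59) had Sesn2 up (0.59 ± 0.0769) and Ddit3 down (-0.55 ± 0.0917), the interferon list (0.959) had Cxcl10 up and Rsad2 down (-0.25 ± 0.0591), and adipose (0.839) had Car3 down (-0.94 ± 0.183). T and NK cell (0.568), circadian clock (0.594), NRF2 (0.618), B and plasma cell (0.63), fatty acid oxidation (0.839) and muscle (0.949) had no call of a gene. The median, the mean and the test differed in sign for the renin-angiotensin, circadian, NRF2, fatty acid and muscle lists.

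In the N-to-N graft, whose podocytes also carried the target, 9 of 25 podocyte genes fell and 4 of 28 cell cycle genes rose, and neither list passed with an estimated correlation (adjusted p = 0.497 and 0.565). Tagln rose from 40.3 ± 1.79 to 89.8 ± 3.56 CPM, a log2 change of 1.15 ± 0.0651 (adjusted p = 3.09e-06). Sema3g, a semaphorin gene of podocytes (ENSMUSG00000021904, chromosome 14, 31217859 to 31230350), fell from 87.3 ± 11.8 to 30.3 ± 1.19 CPM, a log2 change of -1.53 ± 0.0921 (adjusted p = 3.29e-06), and Ddn fell from 13.5 ± 2.41 to 2.83 ± 0.871 CPM (-2.21 ± 0.202, adjusted p = 0.000437). Wt1 and Nphs1 fell by 1.29 ± 0.166 and 0.82 ± 0.125. P2rx7, which encodes an ATP-gated ion channel (ENSMUSG00000029468, chromosome 5, 122643910 to 122691432), rose from 3.92 ± 1.56 to 12.7 ± 2.00 CPM (1.70 ± 0.222, adjusted p = 0.00448), and Ren1 rose from 51.3 ± 11.1 to 95.2 ± 11.8 CPM (0.89 ± 0.149, adjusted p = 0.0205).

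Of 15418 genes tested in the N-to-N graft 109 rose and 78 fell, 32 and 16 of them at least 2-fold, with 2440 at an unadjusted p under 0.05. The authors' own test listed 309, of which 141 were also called here. Other large rises were Thbs4 (log2 change 3.17 ± 0.485), Chek1 (1.77 ± 0.302), Prc1 (1.76 ± 0.357) and Hmmr (1.66 ± 0.34). Other large falls were Nxph3 (-2.02 ± 0.314), Hspa1a (-1.77 ± 0.236), Wt1os (-1.40 ± 0.199), which lies antisense to Wt1, and Rflna (-1.31 ± 0.223). The strand setting of the counting is not given, so reads of Wt1, which fell by 1.29 ± 0.166, are not excluded from the value of Wt1os. Havcr1 was at 22.1 ± 11.3 against 3.55 ± 5.87 CPM (log2 change 2.59 ± 1.09, adjusted p = 0.321). Of its vehicle libraries, library 2 had 12.3 CPM and the other 3 had 0.359 to 1.13 CPM. Lcn2 was at 19.1 ± 6.74 against 4.98 ± 2.91 CPM (1.91 ± 0.443, adjusted p = 0.11). With library totals in place of TMM 236 genes were higher and 64 lower. Without LMB2 library 1 or 2 the count of 187 became 56 or 68, and without vehicle library 1, 2, 3 or 4 it became 92, 323, 93 or 430.

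In the N-to-N graft 9 of 25 podocyte genes fell and Nes rose (13 and 1 when adjusted over the list alone, adjusted p = 2.27e-17, and adjusted p = 0.497 with an estimated correlation). Cell cycle genes rose in 4 of 28, among them Cdc20 (log2 change 1.57 ± 0.299) and Kif20a (1.16 ± 0.227), and 25 rose when adjusted over the list alone (adjusted p = 1.78e-23, and adjusted p = 0.565 with an estimated correlation). In the tubular injury list Il34 rose (0.61 ± 0.132, 11 of 31 when adjusted over the list alone, adjusted p = 4.54e-11, and adjusted p = 0.565 with an estimated correlation). Fibrosis genes rose in 3 of 32, among them Tagln and Vim (0.76 ± 0.0921, 5 when adjusted over the list alone, adjusted p = 1.1e-07, and adjusted p = 0.565 with an estimated correlation). The respiratory chain was lower with none of 24 genes called (5 when adjusted over the list alone, adjusted p = 1.1e-07, and adjusted p = 0.565 with an estimated correlation), and the share of mitochondrial reads was 11.4 ± 0.511% against 13 ± 1.55%. The median exon length of this list was 2249 bases against 3779 in all genes tested. With all genes of this graft in 5 equal classes of exon length, the shortest had a median log2 change of -0.103 and the longest 0.0615, against -0.0984 and 0.0819 in the W-to-N graft. Distal convoluted and connecting tubule genes fell in 2 of 15, Trpm6 (-0.61 ± 0.1) and the calbindin gene Calb1 (-0.78 ± 0.135, 5 when adjusted over the list alone, adjusted p = 5.03e-06, and adjusted p = 0.565 with an estimated correlation). Chemokines and cytokines rose in 2 of 22, Il34 and Csf1 (0.58 ± 0.0948, 7 when adjusted over the list alone, adjusted p = 0.00121). The thick ascending limb list was lower with no call (3 of 14 when adjusted over the list alone, adjusted p = 0.00742), as was the collecting duct list with Slc4a1 (-0.52 ± 0.0783, 3 of 19 when adjusted over the list alone, adjusted p = 0.0426). Both and the chemokine list had adjusted p = 0.565 with an estimated correlation. The cholesterol list was lower (adjusted p = 0.0104, and 0.72 with an estimated correlation) with 1 gene up and Nsdhl down (-0.42 ± 0.0805). With 1 library left out the cholesterol list ended (LMB2 library 3 or 4 or vehicle library 1, adjusted p up to 0.253), as did thick ascending limb (vehicle library 3, 0.0825) and collecting duct lists (LMB2 library 1, 2 or 3 or vehicle library 3 or 4, up to 0.146). Outside called lists, Sesn2 (0.58 ± 0.0962) and Adm (0.70 ± 0.106) rose and Ddit3 (-0.74 ± 0.128), Nr1d1 (-0.65 ± 0.136) and Ehd3 (-0.41 ± 0.0841) fell. Agt, Scnn1a, Scnn1b and Scnn1g did not pass (adjusted p = 0.473, 0.171, 0.925 and 0.428). Median, mean and test differed in sign for the p53, complement, erythroid, urothelium and fatty acid lists.

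In the native kidneys of W-to-N mice, whose podocytes carried the target while those of the graft did not, 9 of 22 immediate early, 6 of 32 fibrosis and matrix and 3 of 22 chemokine and cytokine genes rose. None of these lists passed with an estimated correlation (adjusted p = 0.109, 0.135 and 0.135). Egr1, a transcription factor gene induced by growth factors and stress, rose from 2.49 ± 0.208 to 15.1 ± 4.04 CPM, a log2 change of 2.60 ± 0.198 (adjusted p = 9.93e-05). Tagln rose from 34.0 ± 2.00 to 108 ± 15.3 CPM (1.66 ± 0.104, adjusted p = 1.69e-05) and Vim from 42.7 ± 8.79 to 104 ± 18.3 CPM (1.29 ± 0.163, adjusted p = 0.0144). Sema3g fell from 91.8 ± 20.3 to 37.4 ± 7.65 CPM (-1.30 ± 0.186, adjusted p = 0.0287). Nphs1 and Wt1 had log2 changes of -0.63 ± 0.176 and -0.72 ± 0.177 and did not pass (adjusted p = 0.162 and 0.104). Over the alternatives Nphs1 passed in 2 of 19 (adjusted p = 0.0169 to 0.333) and Wt1 in 3 of 19 (0.00906 to 0.229). Whether the response differed between the native kidneys of W-to-N and N-to-N mice was not tested.

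Of 15448 genes tested in the W-to-N native kidney 72 rose and 20 fell, 30 and 4 of them at least 2-fold, with 2099 at an unadjusted p under 0.05. The authors' own test listed 430, of which 85 were also called here. Other large rises were Timp1 (log2 change 4.94 ± 0.774), Thbs4 (3.65 ± 0.489), Cxcl1 (3.58 ± 0.594), Fos (2.93 ± 0.407) and Lif (2.74 ± 0.403). Other large falls were Banp (-1.24 ± 0.188), the transferrin receptor gene Tfrc (-1.06 ± 0.184), the endothelial gene Esm1 (-0.96 ± 0.138), Akr1d1 (-0.80 ± 0.149) and, with reads of unsettled origin, Kirrel2 (-0.68 ± 0.127). Havcr1 was at 28.1 ± 29.4 against 0.578 ± 0.395 CPM, with 71.6 CPM in LMB2 library 4 and 7.75 to 18.6 CPM in the other 3 (5.58 ± 1.06, adjusted p = 0.104). Lcn2 (3.46 ± 0.619, adjusted p = 0.0799) and Ren1 (0.75 ± 0.187, adjusted p = 0.126) did not pass, nor did Agt, Scnn1a, Scnn1b and Scnn1g (adjusted p = 0.801, 0.853, 0.986 and 0.951). Over the alternatives Havcr1 passed in 4 of 19 (adjusted p = 3.87e-08 to 0.318), Lcn2 in 4 of 19 (6.22e-07 to 0.212) and Ren1 in 2 of 19 (0.0016 to 0.289). Intron reads made up 12.3% in vehicle library 4 of this kidney, against 5.62 to 6.14% in the other 3. Without LMB2 library 1, 3 or 4 the count of 92 became 55, 22 or 42, and without vehicle library 2, 3 or 4 it became 31, 44 or 38.

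Immediate early genes rose in 9 of 22 in the W-to-N native kidney, with Fosl2 at 0.67 ± 0.0807 and Atf3 at 1.36 ± 0.23 (16 when adjusted over the list alone, adjusted p = 8.63e-34, and adjusted p = 0.109 with an estimated correlation). Of 31 tubular injury genes Timp1, Plaur and Tnfrsf12a rose (1.46 ± 0.213 for Tnfrsf12a) and the integrin gene Itgb6 fell by 0.67 ± 0.119 (21 and 1 when adjusted over the list alone, adjusted p = 1.55e-24). Of 32 fibrosis genes 6 rose (10 when adjusted over the list alone, adjusted p = 1.38e-17). Cxcl1, Csf1 (0.83 ± 0.115) and Lif rose among 22 chemokines and cytokines (12 when adjusted over the list alone, adjusted p = 2.42e-15). These 3 lists had adjusted p = 0.135 with an estimated correlation. None of 29 cell cycle genes passed over all genes and 25 rose when adjusted over the list alone (adjusted p = 6.34e-19, and adjusted p = 0.287 with an estimated correlation). In the podocyte list Sema3g fell (2 up and 11 down of 25 when adjusted over the list alone, adjusted p = 9.97e-08, and adjusted p = 0.255 with an estimated correlation). MHC (B2m 0.50 ± 0.0903), interferon, complement and macrophage lists (Csf1r -0.43 ± 0.0765) were higher (adjusted p = 2.75e-07, 3.74e-07, 0.00119 and 0.00298). With an estimated correlation they had adjusted p = 0.309, 0.293, 0.285 and 0.437. The cholesterol list was lower (adjusted p = 1.03e-06, and 0.3 with an estimated correlation). Its member Idi1 was at 112 CPM in vehicle library 1 and 36.1 to 44.3 CPM in the other 3, and without that library the list had adjusted p = 0.00063. So was the proximal tubule list (adjusted p = 0.000437, and adjusted p = 0.444 with an estimated correlation), with a median log2 change of -0.222 and a mean of -0.596. Its member Slco1a1, an organic anion transporter gene, was at 298 CPM in vehicle library 1 of this kidney and at most 6.1 CPM in the other mice. Without vehicle library 1 the proximal tubule list had adjusted p = 0.00234. Distal convoluted and thick ascending limb genes were lower (adjusted p = 0.00316 and 0.00893). Adipose (0.00266), liver (0.00431), neutrophil (0.0148), adrenal (0.0196) and NRF2 genes (0.0319) were higher. These 7 lists had adjusted p = 0.445, 0.437, 0.437, 0.135, 0.204, 0.204 and 0.309 with an estimated correlation. With 1 library left out thick ascending limb (LMB2 library 1 or vehicle library 3, adjusted p up to 0.114), distal convoluted (LMB2 library 4, 0.0632), adipose (LMB2 library 1, 0.0595) and NRF2 lists (LMB2 library 1 or 4 or vehicle library 3 or 4, up to 0.111) ended. Adm (1.02 ± 0.119) and Nos3 (0.57 ± 0.107) rose outside these lists. Median, mean and test differed in sign for the endothelium and B cell lists.

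In the W-to-N graft, whose podocytes did not carry the target, podocyte genes did not pass, and the calls were of other genes with small changes. Nphs1 was at 37.5 ± 2.19 against 36.9 ± 5.06 CPM (log2 change 0.02 ± 0.0931, adjusted p = 0.924). Banp, which encodes a DNA-binding nuclear protein (ENSMUSG00000025316, chromosome 8, 121949749 to 122029258), fell from 27.2 ± 2.89 to 13.8 ± 2.21 CPM, a log2 change of -0.99 ± 0.114 (adjusted p = 0.00787). Cycs, which encodes cytochrome c, fell from 100.5 ± 6.20 to 72.7 ± 1.95 CPM (-0.47 ± 0.0636, adjusted p = 0.0101). Scnn1a, the alpha subunit of the epithelial sodium channel, rose from 142 ± 7.84 to 194 ± 22.9 CPM (0.44 ± 0.0864, adjusted p = 0.0272). Cxcl14 rose from 19.3 ± 1.32 to 30.2 ± 3.18 CPM (0.63 ± 0.0876, adjusted p = 0.0105).

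Of 15565 genes tested in the W-to-N graft 123 rose and 207 fell, 3 and 2 of them at least 2-fold, with a median size of 0.368 on the log2 scale and 3052 genes at an unadjusted p under 0.05. The authors' own test listed 203, of which 151 were also called here. The largest rises were the immunoglobulin gene Ighg2b (log2 change 2.90 ± 0.567), the activin subunit gene Inhbb (1.13 ± 0.237), Adamtsl3 (1.10 ± 0.236), Tcf19 (0.91 ± 0.205), Brca2 (0.76 ± 0.133) and Cygb (0.71 ± 0.146). Ighg2b passed in 6 of 17 alternatives (adjusted p up to 0.102, and 0.0582 with unique exon reads). Lipg fell more than Banp (-1.43 ± 0.3). Other large falls were Pdzrn4 (-0.92 ± 0.176), Tfpi2 (-0.65 ± 0.129), Dusp15 (-0.64 ± 0.119) and Ahsa2 (-0.63 ± 0.12). Inhbb, Adamtsl3, Tcf19 and Lipg passed in 9, 8, 8 and 8 of 17, and Pdzrn4 in 12 of 18. Brca2, Cygb, Tfpi2, Dusp15, Ahsa2 and Scnn1a passed in 14, 12, 12, 14, 11 and 13 of 19. Lcn2 (0.88 ± 0.222, adjusted p = 0.0564), Ren1 (29.2 ± 3.20 against 52.1 ± 25.2 CPM, adjusted p = 0.263), Agt (adjusted p = 0.737), Scnn1b (adjusted p = 0.596) and Scnn1g (adjusted p = 0.438) did not pass. Havcr1 was too low to be tested (0.398 ± 0.117 against 1.17 ± 0.942 CPM). The median exon length was 6786 bases in genes that rose and 1571 in genes that fell, and with a correction for length 43 of the 330 remained past the threshold. The median size of the 330 changes went with it from 0.368 to 0.313 (median SE 0.0739 and 0.0734). With library totals in place of TMM 218 were higher and 135 lower. Without LMB2 library 1, 2 or 4 the count became 20, 49 or 11, and without vehicle library 2, 3 or 4 it became 110, 68 or 62.

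Respiratory chain genes fell in 5 of 24 in the W-to-N graft, with Ndufa1 at -0.34 ± 0.0588 and Cox7c at -0.35 ± 0.0725 beside Cycs (11 when adjusted over the list alone, adjusted p = 2.25e-06, and adjusted p = 0.5 with an estimated correlation). Over the alternatives Ndufa1 passed in 15 of 19 (log2 change -0.367 to -0.22, adjusted p up to 0.141). Cox7c passed in 12 of 19 (-0.393 to -0.188, adjusted p up to 0.22) and Cycs in 19 of 19. In the cholesterol list Mvd fell by 0.53 ± 0.118 (6 of 24 when adjusted over the list alone, adjusted p = 3.24e-05, and adjusted p = 0.5 with an estimated correlation). Its member Idi1 was at 101 CPM in vehicle library 1 and 32.9 to 43.3 CPM in the other 3, and without that library the list had adjusted p = 0.00237. The unfolded protein list was lower with no call (adjusted p = 0.00584, and 0.528 with an estimated correlation). Lists that were higher with 1 call each were MHC (Tap2, 0.36 ± 0.0819, adjusted p = 0.00434), complement (C2, 0.34 ± 0.0817, adjusted p = 0.00584), immediate early (Fosl2, 0.48 ± 0.113, adjusted p = 0.00584), interferon (Ifit2, 0.46 ± 0.11, adjusted p = 0.0174), distal convoluted (Slc16a7, 0.44 ± 0.0963, adjusted p = 0.0198), sodium transport (Scnn1a, adjusted p = 0.0248) and chemokines (Cxcl14, adjusted p = 0.0248). With an estimated correlation these had adjusted p = 0.433 to 0.532. Urothelium, endothelium, circadian clock, tubular injury, macrophage, fibrosis and adipose lists were higher with no call (adjusted p = 0.00263, 0.00434, 0.00665, 0.0198, 0.0229, 0.0278 and 0.0437). With an estimated correlation these had adjusted p = 0.433 to 0.528. The proximal tubule list was lower with no call (adjusted p = 0.0437, and adjusted p = 0.528 with an estimated correlation), with a median log2 change of -0.15 and a mean of -0.463. Its member Slco1a1 was at 259 CPM in vehicle library 1 of this kidney and at most 6.1 CPM in the other mice. Without vehicle library 1 the proximal tubule list had adjusted p = 0.0436. None of 25 podocyte genes passed with edgeR (1 up and 2 down when adjusted over the list alone, adjusted p = 0.945). P4ha1 fell (-0.45 ± 0.0819) and Lnpep (0.50 ± 0.0976) and Myh11 (0.42 ± 0.0826) rose outside called lists. With 1 library left out 8 of the 18 called lists of this graft passed in every case, the respiratory chain and cholesterol lists among them. Proximal tubule, distal convoluted, sodium transport, tubular injury, macrophage, MHC, interferon, chemokine, fibrosis and adipose lists each ended without 1 or more libraries (adjusted p up to 0.323). Each of the 8 libraries ended at least 1 of them. Median, mean and test differed in sign for the p53, renin-angiotensin and adrenal lists.

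The difference of the LMB2 response between N-to-N and W-to-N grafts sets a graft with the target beside a graft without it, in hosts with 2 targeted kidneys and 1. It does not separate the target in the graft from the number of targeted kidneys in the host. Among podocyte genes these fell further in the N-to-N graft: Ddn by 2.19 ± 0.234 on the log2 scale (adjusted p = 9.86e-05), Sema3g by 1.42 ± 0.159 (adjusted p = 0.00022) and Wt1 by 1.31 ± 0.203 (adjusted p = 0.00791). Tagln rose further by 1.19 ± 0.101 (adjusted p = 4.15e-06) and P2rx7 by 1.73 ± 0.312 (adjusted p = 0.0349). In the W-to-N graft these were at 33.3 ± 2.89 against 33.7 ± 2.73 CPM and 3.70 ± 0.741 against 3.77 ± 0.678 CPM.

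Of 16118 genes tested for that difference between grafts 5 were higher and 6 lower, with 1463 at an unadjusted p under 0.05. Tmem37 (0.88 ± 0.148) and Comtd1 (0.86 ± 0.16) were higher, and the class I MHC gene H2-Q6 (-1.39 ± 0.203) and Slc4a1 (-0.67 ± 0.105) lower. Nphs1 (-0.83 ± 0.167, adjusted p = 0.0693), Ren1 (1.74 ± 0.4, adjusted p = 0.22), Lcn2 (1.05 ± 0.537, adjusted p = 0.585) and Havcr1 (4.12 ± 1.72, adjusted p = 0.516) did not pass. Over the alternatives Nphs1 passed in 5 of 27, Ren1 in 2 of 27, and Lcn2 and Havcr1 in 0 of 27. The Havcr1 difference was 3.51 to 6.64 there (adjusted p = 0.0575 to 0.764). Vehicle library 2 of the N-to-N graft was high in Havcr1 (12.3 against 0.359 to 1.13 CPM). Of 25 podocyte genes 3 were lower, among them Wt1 and Sema3g (8 when adjusted over the list alone, adjusted p = 6.23e-14, and adjusted p = 0.1 with an estimated correlation). Cell cycle (5 of 28 when adjusted over the list alone), tubular injury and fibrosis lists were higher (adjusted p = 1.7e-14, 2.4e-06 and 0.00682). With an estimated correlation they had adjusted p = 0.405, 0.495 and 0.742. The distal convoluted list was lower (5 of 15 when adjusted over the list alone, adjusted p = 4.48e-10, and 0.361 with an estimated correlation). The interferon, circadian, macrophage, urothelium, sodium transport, collecting duct, T and NK cell and MHC lists were lower (adjusted p = 0.00235, 0.00304, 0.00682, 0.00764, 0.008, 0.008, 0.00961 and 0.0107). These 8 had adjusted p = 0.495 to 0.758 with an estimated correlation. Without vehicle library 2 of the N-to-N graft the macrophage, T and NK cell, MHC and interferon lists ended (adjusted p = 0.845, 0.43, 0.621 and 0.187). Without vehicle library 1 of that graft the fibrosis list ended (0.369). These lists, but for the macrophage list, and the collecting duct, sodium transport and urothelium lists also ended without other libraries (adjusted p up to 0.151). Median, mean and test differed in sign for the endothelium, muscle, NRF2, erythroid, hypoxia and fatty acid lists. Without vehicle library 2 of the N-to-N graft the count of 11 became 22.

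The difference of the LMB2 response between native and graft kidneys of W-to-N mice sets a kidney with the target beside a kidney without it in the same mice. It does not separate the target from being a native or a transplanted kidney, since only the native kidneys of these mice had the target. Tagln rose further in the native kidney by 1.70 ± 0.138 on the log2 scale (adjusted p = 3.7e-06), P2rx7 by 2.27 ± 0.232 (adjusted p = 8.02e-05), Egr1 by 1.86 ± 0.341 (adjusted p = 0.0329), Vim by 1.07 ± 0.211 (adjusted p = 0.0489) and the cytokine gene Lif by 3.04 ± 0.569 (adjusted p = 0.0329). Kdr, which encodes a receptor of vascular endothelial growth factor, was lower by this measure (-0.67 ± 0.136, adjusted p = 0.0489), at 63.7 ± 9.62 against 93.4 ± 11.2 CPM in the native kidney and 88.0 ± 1.38 against 80.4 ± 6.66 CPM in the graft. Egr1, Vim, Kdr and Lif passed in 12 of 27, 12 of 28, 12 of 28 and 13 of 26 alternatives. Tagln and P2rx7 passed in all. Podocyte genes had no call over all genes.

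Of 16108 genes tested for the difference between native and graft kidneys 32 were higher and 9 lower, with 2093 at an unadjusted p under 0.05. Col5a3 (1.54 ± 0.274), Stc1 (1.49 ± 0.302) and Cycs (0.54 ± 0.107) were higher and Shank2 (-0.55 ± 0.0951), Zfp652 (-0.54 ± 0.109), Trrap (-0.52 ± 0.104), Celsr2 (-0.47 ± 0.0962) and Klhl21 (-0.44 ± 0.0831) lower. Havcr1 (7.10 ± 1.40), Lcn2 (2.59 ± 0.667) and Ren1 (1.60 ± 0.416) had adjusted p = 0.0686, 0.125 and 0.133. With a correction for length 3 of the 41 remained past the threshold, all higher, P2rx7 and Tagln among them. The median size of the 41 log2 differences was 0.553 before and 0.444 after it, with a median SE of 0.104 and 0.107. The median exon length was 1534 bases in the higher genes and 11513 in the lower. With a term for the mouse, 206 were higher and 119 lower and all 41 were kept. With that term alone Havcr1 and Lcn2 had adjusted p = 0.00893 and 0.042, and Ren1 passed as well. Over all alternatives Havcr1 passed in 5 of 27 (adjusted p = 0.00815 to 0.314), Lcn2 in 1 of 27 (0.042 to 0.331) and Ren1 in 2 of 28 (0.0111 to 0.291). With the term and the length correction together 36 were higher and 25 lower, with 15 of the 41 kept. Tubular injury (13 of 31 when adjusted over the list alone, adjusted p = 1.39e-14), cell cycle (adjusted p = 8.42e-12), immediate early (7 of 22 when adjusted over the list alone, adjusted p = 7.64e-09), fibrosis (7 of 32 when adjusted over the list alone, adjusted p = 6.84e-07) and chemokine lists (adjusted p = 3.65e-05) were higher. These had adjusted p = 0.234, 0.264, 0.234, 0.246 and 0.246 with an estimated correlation. Distal convoluted and podocyte lists were lower (both adjusted p = 1.6e-05, and adjusted p = 0.246 with an estimated correlation), the podocyte list with 1 up and 6 down of 25 when adjusted over the list alone. Respiratory chain, unfolded protein and NRF2 lists were higher (adjusted p = 0.00183, 0.00533 and 0.00709) and urothelium, sodium transport and endothelium lists lower (adjusted p = 0.000691, 0.000721 and 0.00536). The last 6 lists had adjusted p = 0.246 to 0.329 with an estimated correlation. With the term for the mouse all 13 lists passed, and 4 more did: interferon, fatty acid and liver higher (adjusted p = 0.0388, 0.0379 and 0.0251) and circadian clock lower (adjusted p = 0.0243). With that term and an estimated correlation none of the 17 passed (adjusted p = 0.32 to 0.709). The unfolded protein list ended without native vehicle library 4 (0.0567). Signs of median, mean and test differed for the muscle, cholesterol and hypoxia lists. Without graft LMB2 library 1, 2 or 4 the count of 41 became 4, 9 or 4, without graft vehicle library 1, 2, 3 or 4 it became 11, 25, 4 or 5. Without native LMB2 library 3 or 4 it became 26 or 10, and without native vehicle library 2 or 3 it became 5 or 14.

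Under vehicle, Kirrel2 was nearly absent from wild-type grafts and present in all kidneys of NEP25 origin. Kirrel2 encodes a nephrin-like protein and lies 623 bases from Nphs1 on chromosome 7 (ENSMUSG00000036915, 30447533 to 30457690). The NEP25 transgene is driven by the nephrin promoter, and the counts do not settle whether Kirrel2 reads came from the gene itself or from sequence carried with the transgene. This holds for every value of Kirrel2 given here. Kirrel2 was at 0.291 ± 0.132 CPM in the W-to-N graft, 26.3 ± 3.22 in the N-to-N graft, 37.5 ± 4.84 in the W-to-N native kidney and 33.0 ± 3.69 in the N-to-N native kidney. Under LMB2 it was at 0.0939 ± 0.111, 18.5 ± 2.58, 23.3 ± 4.07 and 19.5 ± 0.997 CPM. Graft against native kidney in W-to-N mice gave a log2 difference of -7.00 ± 0.208 (adjusted p = 1.38e-08), and N-to-N against W-to-N graft gave 6.48 ± 0.214 (adjusted p = 1.95e-09).

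Otherwise these kidneys hardly differed under vehicle by the test of single genes. Of 15585 genes in graft against native kidney Kirrel2 and the numbered gene Gm9800 were lower and 0 higher with edgeR, with 1423 at an unadjusted p under 0.05 and 26 calls with DESeq2. Of 15490 genes in N-to-N against W-to-N grafts, Kirrel2 alone was called with edgeR, with 1983 at an unadjusted p under 0.05 and 127 calls with DESeq2. Nphs1 and Ren1 did not pass (adjusted p = 0.521 and 0.54 for graft against native, and 0.285 and 0.976 between grafts). Graft against native kidney had lower endothelium and fibrosis lists and a higher collecting duct list (all adjusted p = 0.0432, and adjusted p = 0.833 with an estimated correlation). With a term for the mouse these 3 passed, and distal convoluted (higher), renin-angiotensin and cholesterol lists (lower) as well (adjusted p = 0.0286, 0.0286 and 0.0402). All 6 had adjusted p = 0.826 with that term and an estimated correlation. The first 3 each ended without graft library 2, and without some other libraries of either kidney (adjusted p up to 0.37). N-to-N against W-to-N grafts had higher fibrosis (median log2 difference 0.311, adjusted p = 2.41e-09), MHC and macrophage (both adjusted p = 1.64e-06), complement (0.000154), interferon (0.00068), fatty acid (0.00242), chemokine (0.00511), T and NK cell, circadian and immediate early (all 0.00516), tubular injury (0.00646) and NRF2 lists (0.0106). They had lower cholesterol (0.00242), erythroid (median -2.02, 0.00511) and collecting duct lists (0.0356). All 15 had adjusted p = 0.572 to 0.581 with an estimated correlation. Without N-to-N library 2, 9 of these 15 ended (adjusted p = 0.079 to 0.618), the cholesterol list among them. That list also ended without W-to-N library 1 (0.0575), where Idi1 was at 101 CPM, and the collecting duct list without W-to-N library 2 or 3 or N-to-N library 1 (up to 0.379). Over all genes no member of these lists passed with edgeR. The proximal tubule list had a median of 0.00877 and a mean of -0.316, with Slco1a1 at 259 CPM in library 1 of the W-to-N graft. Signs also differed for the thick ascending limb and hypoxia lists between grafts, and for the hypoxia, circadian, sodium transport and liver lists of graft against native kidney. Without W-to-N graft library 1, 2 or 3 the count of 2 became 1, without native library 1, 3 or 4 it became 1, 1 or 5. Between grafts the count of 1 became 2 or 35 without W-to-N library 1 or 4 and 3 without N-to-N library 2.

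Genes called under LMB2 overlapped between kidneys. The N-to-N graft and N-to-N native kidney, which came from the same mice, shared 75 higher and 51 lower genes, where 2.67 and 1.22 are expected by chance (Fisher's exact p = 4.26e-97 and 1.12e-74). Native kidneys of W-to-N and N-to-N mice shared 49 higher and 7 lower genes, with 1.78 and 0.316 by chance (exact p = 1.55e-62 and 1.48e-08). The N-to-N graft and W-to-N native kidney shared 21 and 2, with 0.512 and 0.103 by chance (exact p = 5.67e-29 and 0.00465). The W-to-N graft shared 7 higher and 6 lower genes with the N-to-N graft (0.841 and 1.06 by chance, exact p = 2.12e-05 and 0.000674), 4 and 4 with the W-to-N native kidney of the same mice (0.549 and 0.258 by chance, exact p = 0.00222 and 0.00011), and 9 and 8 with the N-to-N native kidney (2.84 and 3.28 by chance, exact p = 0.00221 and 0.0175). These are overlaps across genes, which are not independent replicates. Where both kidneys came from the same mice, differences between mice enter both sets of calls, and the chance values leave this out.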

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

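The test of transcript length in the W-to-N graft was chosen only after the result was seen. The counts of other splits of the libraries were planned.

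In the W-to-N graft the genes that rose under LMB2 were long and those that fell were short, with median exon lengths of 6786 and 1571 bases against 3761 in all genes tested. A length bias between libraries could give this pattern: with a correction for length 13% of the called genes (43 of 330) remained past the threshold. The median size of the 330 log2 changes went from 0.368 to 0.313 in the same direction (median SE 0.0739 and 0.0734). The 287 calls that ended had a median adjusted p of 0.0369 before and 0.082 after (highest 0.294), and genes at an unadjusted p under 0.05 went from 3052 to 2567. The median of 0.313 does not decide on a length bias as the whole cause, since the 330 genes were picked for large uncorrected changes. For the trend with length itself, a bias and a response of short genes, such as those of the respiratory chain (median 2249 bases), cannot be told apart, since the correction takes out the trend whatever its origin. The N-to-N graft had nearly the same trend, with a Spearman correlation of length and log2 change across genes of 0.251 against 0.273 (genes are not independent replicates). The W-to-N native kidney went the other way (-0.108) and the N-to-N native kidney had -0.00462. In the other 3 kidneys 176 of 187, 83 of 92 and 587 of 622 calls remained with the correction.

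Other splits of the 8 libraries into 4 and 4 made chance unlikely for 3 of the counts of LMB2 against vehicle. They cannot exclude it, since 1 of 35 is the smallest share possible and the tests were not adjusted over the 8 comparisons. Of 35 splits only the real one (1 of 35) gave as many genes in the W-to-N graft (330, highest other 2), the W-to-N native kidney (92, highest other 2) and the N-to-N native kidney (622, highest other 3). In the N-to-N graft 2 of 35 splits gave as many as the real 187, and the other gave 846. That split exchanged LMB2 library 4 with vehicle library 4 and called several times the real count, which points to a structure of these samples, and chance is not excluded for that count. The slope of expression on log2 exon length set both libraries apart from their groups: -0.0102 against 0.0445 to 0.0516 in the other LMB2 libraries, and 0.0344 against -0.0532 to -0.0076 in the other vehicle libraries. Podocyte genes followed the labels, with Sema3g at 30.62 CPM in LMB2 library 4 and 100.7 CPM in vehicle library 4, so an exchange of these libraries is not shown. The labels give no batch, and a batch of these libraries was not tested. For the difference between N-to-N and W-to-N grafts 1 of 100 drawn splits gave as many (11, highest other 9). For the difference between native and graft kidneys it was 1 of 35 (41, highest other 0). Chance was made less likely for both and not excluded, and for the grafts the highest other of 9 was close to 11. Under vehicle 5 of 35 splits gave as many as 2 genes for graft against native kidney (highest other 34) and 5 of 35 as many as 1 gene between grafts (highest other 1), and chance is not excluded. Among the 8 splits that part all 4 mice's kidneys, 2 gave as many for graft against native, and the highest other was 34.

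Past the threshold were 23 differences of the LMB2 response in 21 named genes, with P2rx7 and Tagln in both comparisons. Between N-to-N and W-to-N grafts they were log2 differences of 1.73 for P2rx7, 1.19 for Tagln, 0.879 for Tmem37, 0.862 for Comtd1, -2.19 for Ddn, -1.42 for Sema3g, -1.39 for H2-Q6, -1.31 for Wt1 and -0.669 for Slc4a1. Between native and graft kidneys of W-to-N mice they were 2.27 for P2rx7, 1.86 for Egr1, 1.70 for Tagln, 1.54 for Col5a3, 1.49 for Stc1, 1.07 for Vim, 3.04 for Lif, 0.535 for Cycs, -0.666 for Kdr, -0.553 for Shank2, -0.542 for Zfp652, -0.516 for Trrap, -0.469 for Celsr2 and -0.439 for Klhl21.

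In 19 of 332 groups of 4 libraries a single library stood far from the other 3, where about 5% are expected by chance. The measure was its gap to the nearest other over the whole range, above the critical value of Dixon's test. Intron reads in vehicle library 4 of the W-to-N native kidney had 0.922 (12.3% against 5.62 to 6.14%). In the W-to-N graft Ighg2b had 0.852 in LMB2 library 2 (8.06 against 1.81 to 2.74 CPM), Inhbb 0.955 in vehicle library 1 (1.2 against 2.12 to 2.16), Lipg 0.89 in LMB2 library 1 (0.468 against 1.52 to 1.65) and C2 0.95 in vehicle library 1 (37.3 against 48.4 to 49). In the N-to-N graft Thbs4 had 0.857 in LMB2 library 3 (3.42 against 5.28 to 5.59 CPM), Il34 0.861 in vehicle library 3 (7.3 against 9.22 to 9.53), Csf1 0.944 in vehicle library 1 (11.4 against 13.9 to 14.1) and 0.847 in LMB2 library 1 (21.9 against 19.1 to 19.5), Havcr1 0.936 in vehicle library 2 (12.3 against 0.359 to 1.13), and Ddit3 0.852 in LMB2 library 4 (22.9 against 16.6 to 17.6). In the W-to-N native kidney Fos had 0.877 in vehicle library 3 (0.748 against 0.321 to 0.374 CPM), Nphs1 0.867 in LMB2 library 4 (20.9 against 33.3 to 35.2) and Havcr1 0.8294 in LMB2 library 4 (71.6 against 7.75 to 18.6). In the N-to-N native kidney Slc12a3 had 0.932 in vehicle library 3 (923 against 972 to 976 CPM), Cxcl10 0.867 in vehicle library 2 (4.67 against 2.38 to 2.68), C3 0.959 in LMB2 library 2 (96.6 against 250 to 257), Tagln 0.87 in vehicle library 2 (29.5 against 35.7 to 36.6) and Adm 0.909 in LMB2 library 1 (10.5 against 11.3).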

How the results depend on the processing

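The tests with unique exon reads, total exon reads, the length correction, that correction with a block, an estimated correlation with a block, and limma-voom were chosen after seeing the data, and the other alternatives were planned. No named gene that was called changed direction, and 34 sign changes were in 10 log2 changes that were not called and lay within 1 SE of 0. The majority direction of counts did change. In the N-to-N graft 109 higher and 78 lower became 255 and 282 with shared spread, and 46 and 47 or 185 and 245 without vehicle library 3 or 4. In the W-to-N graft 123 and 207 became 218 and 135 with library totals, and 3 and 2 with the 2-fold minimum. Graft against native under vehicle went from 0 and 2 to 3 and 2 with the block and length correction. Between grafts under vehicle 1 and 0 became 33 and 94 with DESeq2, and mostly lower genes in 4 other settings. Of the named genes' values, 413 of 595 stayed on the same side of the threshold in the W-to-N graft, 570 of 654 in the N-to-N graft, 492 of 602 in the W-to-N native kidney, 930 of 1032 in the N-to-N native kidney. They were 306 of 351 and 279 of 467 in the differences of responses between grafts and between native and graft kidneys, and all 60 and 57 under vehicle. Named genes called under every setting numbered 31 in the N-to-N native kidney, 10 in the N-to-N graft (with Nphs1, Wt1 and Tagln), 7 in the W-to-N native kidney, 3 in the W-to-N graft (Banp, Cxcl14 and Cycs), 5 in the difference between grafts and 2 (P2rx7 and Tagln) between native and graft kidneys. Genes near 1 CPM, such as Havcr1 under vehicle, rested on few reads. DESeq2, voom and the length correction were not run for gene lists, and alternatives of the pseudocount do not apply to counts. Unless stated, the cause of a change was not tested.

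A stricter threshold or a minimum fold keeps fewer genes by construction. At 0.01 the counts were 2 for the W-to-N graft, 46 for the N-to-N graft, 5 and 193 for the W-to-N and N-to-N native kidneys, 7 for the difference between grafts, 4 for that between native and graft kidneys, and 1 for graft against native under vehicle. With a 2-fold minimum they were 5, 48, 34, 134, 7 and 7 in the first 6 of these. DESeq2 gave 831, 541 and 496 for the W-to-N graft, N-to-N graft and W-to-N native kidney, 60 and 282 for the differences, and 26 and 127 for graft against native and between grafts under vehicle. With no filter the counts were 674, 400 and 296, then 22 and 21, then 4 and 106. Library totals gave 300 in the N-to-N graft. A mean of at least 5 CPM gave 54 in the W-to-N native kidney, 78 for native against graft responses and 1 for graft against native under vehicle. The block gave 65 in the N-to-N graft and 392 in the W-to-N native kidney by replicate number, 325 for native against graft responses by mouse, and 29 between grafts under vehicle. Spread shared over all groups gave 537 in the N-to-N graft, 550 in the W-to-N native kidney, 15 for native against graft responses and 65 between grafts under vehicle. Total exon reads gave 64 for native against graft responses, and unique exon reads 1 for graft against native under vehicle. The length correction gave 43 in the W-to-N graft and 3 for native against graft responses, and with the block 61 (15 shared with the 41) and, under vehicle, 5 for graft against native. Voom gave 24 for native against graft responses and 1 for graft against native under vehicle.

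Of called lists (18, 10, 19, 20, 13, 13, 3 and 15, in the order W-to-N graft, N-to-N graft, W-to-N native, N-to-N native, the 2 differences and the 2 comparisons under vehicle), the estimated correlation left 0, 0, 0, 4, 0, 0, 0 and 0, and with the mouse as block 0 in native against graft responses and 0 in graft against native under vehicle. With fry 0 were left in each graft, 6 in the W-to-N native kidney, 1 and 4 in the differences, and 0 and 0 under vehicle. With no filter 16 lists were called in the N-to-N graft. For graft against native under vehicle the lists were 0 with library totals, 5 with no filter, 1 at 5 CPM, 6 with the mouse as block, 0 with shared spread, and 1 and 1 with unique and total exon reads.

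Leaving out each library in turn gave 11 to 403 genes in the W-to-N graft, 56 to 430 in the N-to-N graft, 22 to 70 in the W-to-N native kidney, 290 to 692 in the N-to-N native kidney, 8 to 22 for the difference between grafts, 4 to 52 for that between native and graft kidneys, 1 to 5 for graft against native and 1 to 35 between grafts under vehicle. Lists ranged 9 to 19, 9 to 14, 17 to 22, 17 to 21, 9 to 14, 12 to 17, 0 to 7 and 8 to 19 in the same order. Libraries that moved a count over 1.5 times stand beside each count in the results by group.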

Other observations

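The comparisons over mice of the genes called in all kidneys and of the heat shock genes, and the test of the intron share in the 2 kidneys of a mouse, were chosen only after the result was seen. The tests of temperature, circadian phase, androgen-responsive genes and sex were written before their results.

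Only 3 genes passed in all 4 comparisons of LMB2 with vehicle, the wild-type graft included, with edgeR. Banp fell (log2 changes -0.99, -1.04, -1.24 and -1.21 in the W-to-N graft, N-to-N graft, W-to-N native and N-to-N native kidneys). Sema3f, which encodes a secreted semaphorin (ENSMUSG00000034684, chromosome 9, 107681499 to 107710475), rose by 0.37, 0.65, 0.46 and 0.60, and Inhbb, which encodes a subunit of inhibin and activin (ENSMUSG00000037035, chromosome 1, 119415464 to 119422248), by 1.13, 1.44, 1.78 and 1.75. With the kidneys of each mouse averaged, Banp was at 13.7 ± 3.14 CPM in 8 LMB2 mice and 29.5 ± 3.21 CPM in 8 vehicle mice (log2 difference -1.13 ± 0.133). No library overlapped between arms for Banp, at 8.83 to 18.7 CPM under LMB2 and 21.1 to 34.4 CPM under vehicle, or for Sema3f, at 25.9 to 36.4 and 17.8 to 23.8 CPM. Inhbb overlapped, with 2.93 CPM in its lowest LMB2 library and 4.24 CPM in its highest vehicle library, and in the W-to-N graft it passed in 9 of 17 other settings. These genes were picked by their calls in the same libraries, so the values over mice are no further evidence. Another 22 genes were higher and 3 lower in exactly 3 of the 4 comparisons.

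Some heat shock genes, picked after their values were seen and not from a list fixed in advance, had lower means in LMB2 mice. Over 8 mice per arm Hsph1 was at 161 ± 13.1 against 249 ± 52.7 CPM (log2 difference -0.607 ± 0.116), Hspa1a at -1.47 ± 0.318, Dnajb1 at -0.706 ± 0.136, Dnaja1 at -0.486 ± 0.0774, Chordc1 at -0.402 ± 0.0579, Hsp90aa1 at -0.266 ± 0.0696 and Hspa8 at -0.198 ± 0.062. By kidney Hsph1 passed in the N-to-N graft and the N-to-N native kidney (adjusted p = 0.0022 and 0.0002), not in the W-to-N graft and native kidney (adjusted p = 0.182 and 0.316).

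A lower body temperature of the LMB2 mice could lower such genes, and would raise the cold-inducible genes Cirbp and Rbm3. Their mean log2 difference was 0.067 ± 0.0761, above 0 in 4 of 8 values, which does not decide. The test of a different circadian phase at harvest does not decide either. With Dbp and Arntl as covariates the difference of Hsph1 was -0.478 ± 0.187, still more than 2 SE below 0, against -0.607 ± 0.116 without them. Covariates of 2 genes may take out only part of a phase difference, and Hsph1 was picked after its values were seen. The mean of 8 clock genes differed by 0.0321 in W-to-N and -0.24 in N-to-N mice, with SDs of 0.223 and 0.225. Arntl by itself was lower under LMB2 (-0.816 ± 0.267, exact permutation p = 0.00857, adjusted over 16 tests 0.0105), and Dbp was not (0.132 ± 0.245). These genes did not move together, so their mean can hide a shift of phase. Body temperature, circadian phase, and a response of the whole animal to podocyte injury or to LMB2 itself, stay open and were not measured.

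Some genes were alike in the 2 kidneys of a mouse. After removal of group means 436 of 14380 genes had r above 0.8 between graft and native kidney over 16 mice, where 100 other pairings of the kidneys gave a median of 4 and at most 15. Prlr, which encodes the prolactin receptor (ENSMUSG00000005268, chromosome 15, 10177237 to 10349180), had r = 0.993. This r and the count of 436 may rest on mouse 5 and were not taken without it. In mouse 5 (vehicle library 1 of the W-to-N graft and native kidney) Prlr was at 9.17 and 10.6 CPM, against 196 to 224 CPM in the other vehicle W-to-N mice. Slco1a1 was at 259 and 298 CPM against at most 6.1 CPM, and the androgen-responsive gene Kap at 11700 and 10800 CPM against 1580 to 3600 CPM in those mice.

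Different androgen levels between mice are a candidate explanation for the likeness of Prlr. Other genes alike in both kidneys followed Prlr inversely (Slco1a1, r = -0.96) or hardly (Aqp2 and Igha, r = 0.0372 and 0.0869). Over 16 mice Prlr went against the mean of Kap, Cyp4a12a, Cyp7b1 and Gusb, with Pearson's r = -0.924 (permutation p = 0.00161, adjusted over 2 relations 0.00322) and Spearman's rho = -0.824 (permutation p = 0.00458, adjusted 0.00916), r = -0.713 without the 2 farthest mice, and r = -0.773 and rho = -0.786 without mouse 5. A library batch shared by both kidneys of a mouse could make their intron shares alike. These had r = -0.378 (permutation p = 0.434, adjusted 0.434) and rho = -0.0441 (permutation p = 0.901, adjusted 0.901), with r = -0.405 without the 2 farthest. No likeness of the intron shares was thus seen, and a batch that does not act on the intron share was not tested. Mice of both sexes are excluded by Y-linked genes, whose lowest sum was 89.4 CPM in native kidneys, with Xist at most 0.639 CPM. Hormones were not measured, so the androgen explanation stays a hypothesis.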
